A study of Mus musculus with 4 samples.

How the data were processed

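Total RNA of male mouse bladders was labelled with biotin and hybridised to Illumina arrays, per the labels. The labels place 2 arrays in a sham group and 2 in a group obstructed for 14 days, and number the arrays as replicates 1 and 2 within each group. The titles also give each array a further number of its own, different in all 4, without saying what it stands for. The deposited table of the authors holds 1 value per probe and array for 46657 probes, and its columns were matched to the samples by their names. The values deposited by the authors are log2 intensities, as judged from their range of 4.14 to 15.63, since no header or label states the scale. The 4 columns held nearly the same sorted values, with a largest difference of 0.0252, which is what quantile normalization leaves, and each had a median of 5.80. Background correction, scanner software and any filter are not given in the sources used here, and no detection p-values were used. A low value can therefore not be told apart from background by a stated test, and differences between dim values may understate changes.

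Gene names came from the platform's annotation of the probes. Of the probes, 22380 had 1 gene symbol, 0 had several and 24277 had none, and the latter are unnamed here. All 22380 gene numbers were found in the RefSeq gene table, and 0 symbols changed. For the 5141 genes with more than 1 probe, the probe with the highest mean over the 4 arrays was used, which left 15366 genes. Of 47 named genes with more than 1 probe, 28 had at least 2 probes above the median of all probes, and in 3 of these, Elf3, Ikbkb and Pacsin3, such probes differed in sign. There were 0 columns of values left unused.

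Obstructed was compared with sham in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a trend of the variance on the mean, on the log2 values as deposited. No filter on dim probes was applied, and no floor was needed since the values were already on a log scale. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 15366 genes, and an adjusted p below 0.05 was called. Intervals are 95% intervals of the same fit. Differences are always obstructed minus sham. The groups were fitted with 1 common spread per gene. Gene lists for processes and cell types were fixed before the data were examined, as were the test, the naming rule and the alternatives, unless stated otherwise. The 34 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over all lists, and members were also adjusted over the list alone. Camera with a correlation estimated per list, and fry, were run beside it. The median change of all genes was -0.0157.

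The genes named were, per direction, the 12 with the largest change among those called whose groups did not overlap and whose higher mean lay above the median of all probes, filled up with the largest changes at an unadjusted p below 0.05 where fewer qualified. Every measured member of the caveolin, GATA and NF-kB subunit lists was named, and from each other list up to 4 members with the smallest p. Uncharacterised genes were skipped in the first part of the rule. The NF-kB genes Nfkb1 and Chuk were not analysed here, having no probe named for them.

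The scripts were tested on simulated data for 15366 genes with the means of the real genes and a spread drawn from the fit. In 5 simulations of obstructed against sham with 100 genes changed 2-fold and 100 changed 4-fold, 27.6% of the former and 89.6% of the latter were called, with 7.6 false calls among 124.8 on average. A list shifted by 1 log2 unit was found in 5 of 5 simulations, with 0.2 other lists called on average. These simulations assumed the same spread in both groups.

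Alternatives were quantile normalization, centring of each array on its median, a floor of 50 on the linear scale, a filter on genes with a mean below the median of all probes, the mean of all probes of a gene, every probe tested on its own, eBayes without the trend and with a robust trend, an unmoderated fit, the replicate number as a block, each array left out in turn, a minimum of 2-fold, and an adjusted p below 0.1. Weights per array estimated by limma were added after seeing the data. Tests that set cell type markers against each other or against contractile genes left out genes with a mean below the median of all probes, a choice made after seeing the data. For the spread of cell type medians, genes were permuted among 10 lists, those of urothelium, accessory glands, adipocytes and skeletal muscle being left out, and a larger spread was counted. Permutation tests, two-sided and over genes, with 100000 resamples or exact, and figures were made in Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.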

Results

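RNA of mouse bladder was measured on single-colour Illumina arrays in males that had undergone either partial bladder outlet obstruction, an operation that makes the bladder empty against a raised resistance, or a sham operation. There were 2 arrays per group, the obstructed bladders being taken at 14 days. Each array gave a value for 46657 probes, and after choosing 1 probe per gene 15366 named genes were compared. Values ran from 4.14 to 15.63 on the log2 scale with a median of 5.80 in each array. The labels do not say whether each array carried the RNA of a separate mouse, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: with 2 per group, standard errors rest on 6.04 degrees of freedom after moderation by limma. Across all probes the sham arrays correlated at 0.989 with each other and the obstructed arrays at 0.969. Obstructed replicate 1 correlated with the sham arrays at 0.982 and 0.981, and obstructed replicate 2 at 0.961 and 0.962.

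After obstruction, 4 genes rose and 4 fell. Ltbp2, which encodes a secreted protein bound to elastic fibres, rose 13.0-fold, from 7.29 ± 0.05 to 10.99 ± 0.18 (log2 value, SD, n = 2), a log2 change of 3.70 with a standard error of 0.21. Rgs4, a regulator that shortens signalling through G proteins, rose 7.94-fold (log2 change 2.99, SE 0.21), Ankrd1, a stretch-responsive protein of striated muscle, rose 4.89-fold (2.29, SE 0.19), and Grem1, a secreted antagonist of bone morphogenetic proteins, rose 4.72-fold (2.24, SE 0.18). Cyp2e1, a cytochrome P450 enzyme, fell 20.2-fold, from 10.04 ± 0.31 to 5.70 ± 0.30 (SD, n = 2), a log2 change of -4.34 with a standard error of 0.25. Npy6r, a receptor of the neuropeptide Y family, fell 7.38-fold (log2 change -2.88, SE 0.21), Dbp, an output transcription factor of the circadian clock, fell 4.75-fold (-2.25, SE 0.18), and Tcap, a protein of the sarcomeric Z-disc, fell 4.56-fold (-2.19, SE 0.18). By limma with Benjamini-Hochberg adjustment over the 15366 genes, the adjusted p was 0.0165 for Ltbp2 and Cyp2e1, 0.0317 for Rgs4 and Npy6r, and 0.0349 for Ankrd1, Grem1, Dbp and Tcap. Their probes were 4850039 for Ltbp2, 2970711 for Rgs4, 4850685 for Ankrd1, 3940180 for Grem1, 103290400 for Cyp2e1, 4560136 for Npy6r, 4200270 for Dbp and 4890446 for Tcap. A dimmer probe of Ltbp2, with a mean of 5.42, differed by -0.02, and another probe of Cyp2e1 by -3.51.

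At an unadjusted p below 0.05 the same fit gave 469 genes higher and 782 lower, where 768.3 in all would be expected by chance. The groups did not overlap for 2712 genes that were higher and 3316 that were lower, 39.2% of all genes against 33.3% by chance. Leaving out sham replicate 1 or sham replicate 2 left 0 genes called by limma in each case, with 215 higher and 373 lower, and 202 higher and 388 lower, at an unadjusted p below 0.05. Leaving out obstructed replicate 1 gave 519 genes higher and 780 lower, and leaving out obstructed replicate 2 gave 154 higher and 169 lower, each including the 8 genes named. In these fits the lone array is assumed to vary like the arrays of the other group. With values floored at 50 on the linear scale, or with an unmoderated fit per gene, limma called 0 genes, against 490 higher and 759 lower, and 463 higher and 598 lower, at an unadjusted p below 0.05.

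Other large differences did not pass the test. Actc1, the cardiac form of actin, measured 12.96 ± 0.18 in sham and 8.85 ± 1.28 in obstructed bladders (log2, SD, n = 2), a difference of -4.11. Adipoq, the adipocyte hormone adiponectin, differed by -4.00 and had an adjusted p of 0.0662 by limma. Ppp1r1a, an inhibitor of protein phosphatase, differed by -2.77, Pck1, an enzyme of gluconeogenesis, by -2.73, and Eno3, the muscle form of enolase, by -2.65. The troponin genes Tnnt3 and Tnnt2 differed by -2.36 and -2.20, and Mbp, a myelin protein, by -2.22. Among genes that were higher, the largest differences that did not pass were those of Svs2, Svs4, Svs5, Msmb, Defb50, Svs1, Svs6 and Sbp, between 5.26 and 6.76, all secretory genes of the male accessory glands that are described with that list.

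The title of the series asks about transcription of the caveolins, which form the membrane pits called caveolae, and about 2 regulators, GATA-6 and NF-kB. None of the 10 measured genes of caveolins and caveola coats passed the test over all genes, and Cavin2 was the 1 that passed when adjusted over the list alone. Cav1 measured 13.95 ± 0.19 in sham and 13.39 ± 0.42 in obstructed bladders (log2, SD, n = 2; probe 870025). The log2 change of Cav1 was -0.56 (SE 0.22, 95% interval -1.10 to -0.02), 1.47-fold lower, with an adjusted p of 0.601 by limma and 0.0899 over the list alone. Cav2 and Cav3 differed by -0.74 (SE 0.24) and -0.58 (SE 0.19), with an adjusted p of 0.0602 over the list alone for each. Of the cavins, which coat caveolae, Cavin2 differed by -1.12 (SE 0.25, limma adjusted p = 0.331, and 0.0422 over the list alone), Cavin1 by -1.10, Cavin3 by -0.63 and Cavin4 by 0.08. The membrane-shaping genes Pacsin3, Ehd2 and Pacsin2 differed by 0.45, 0.24 and 0.00. Ehd2 and Pacsin2 lay below the median of all probes, 5.80, in every array, so that their values say little. Dimmer probes of Pacsin3 lay between -0.23 and 0.05, and a dimmer probe of Cav2 at -0.07.

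As a list, the caveola genes had a median log2 change of -0.57 and did not pass camera (adjusted p = 0.0514; adjusted p = 0.712 with an estimated correlation). It passed camera with genes below the median brightness removed (adjusted p = 0.0200) with all probes of a gene averaged (adjusted p = 0.0167) and without sham replicate 1 (adjusted p = 0.0152), but not without sham replicate 2 (adjusted p = 0.271), and over the alternatives its camera adjusted p with the preset correlation ran from 0.00253 to 0.321. The arrays differed in this respect, with a list median of -0.16 in obstructed replicate 1 and -0.76 in obstructed replicate 2. Cav1 differed from the sham mean by -0.26 in obstructed replicate 1 and by -0.86 in obstructed replicate 2, and Cavin3 by -0.06 and -1.19. With obstructed replicate 2 alone against the sham arrays, the limma adjusted p of Cav1 was 0.00225 and the camera adjusted p of the list 0.00253, and with obstructed replicate 1 alone they were 0.516 and 0.112. Cav3, Cavin1, Cavin2 and Cavin3 also passed with obstructed replicate 2 alone, and Cavin2 with obstructed replicate 1 alone (limma adjusted p = 0.0496). Secretory genes of male accessory glands were also highest in obstructed replicate 2, with a list median of 8.06 above sham against 1.65 in replicate 1.

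**Figure D1:**
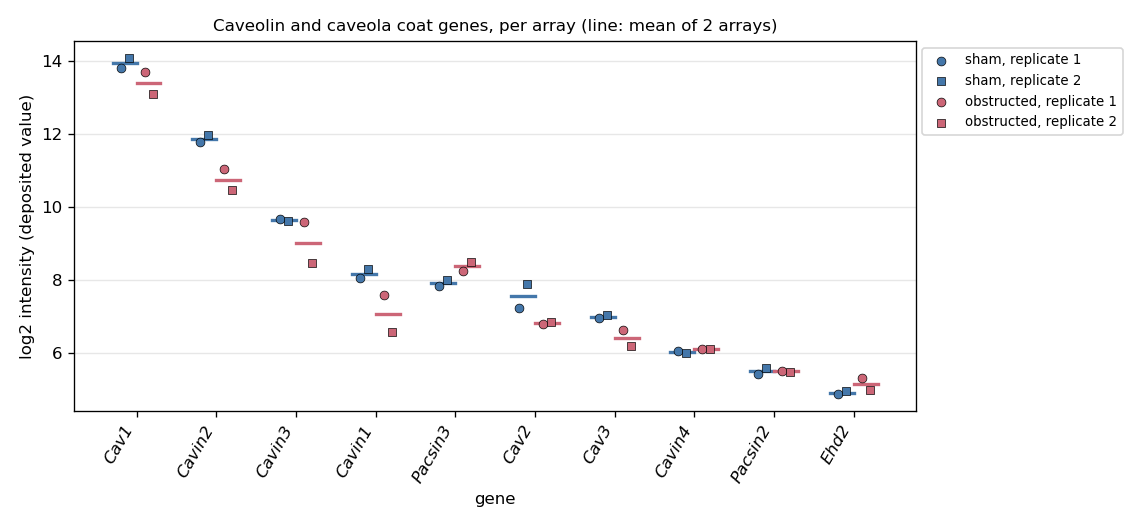
Deposited log2 intensity (vertical axis) of the caveolin and caveola coat genes (horizontal axis) in each array, with sham in blue, obstructed in red, circles for replicate 1 and squares for replicate 2; lines are means of 2 arrays. Cav1 averages 13.95 in sham and 13.39 in obstructed bladders, and Cavin1, Cavin2 and Cavin3 lie lowest in obstructed replicate 2.

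Gata6 measured 10.74 and 10.83 in the sham arrays and 10.34 and 9.67 in the obstructed arrays (log2 values, probe 1770010). Its log2 change was -0.78 (SE 0.27), with an adjusted p of 0.550 by limma and 0.231 over the list alone, and it was -0.44 in obstructed replicate 1 and -1.12 in obstructed replicate 2. With obstructed replicate 2 alone against the sham arrays Gata6 passed (limma adjusted p = 0.00429), as did its cofactor Zfpm2, at -0.93 (adjusted p = 0.00947), and with obstructed replicate 1 alone neither did (0.406 and 0.851). Of the 8 GATA factors and cofactors measured, 0 passed over all genes or over the list alone, the other members ranging from -0.43 for Gata4 to 0.23 for Gata2, with Zfpm2 at -0.39, Gata3 at -0.26, Gata5 at -0.12, Gata1 at -0.10 and Zfpm1 at 0.00. The list median was -0.19 (camera adjusted p = 0.215). The NF-kB subunits and kinases, of which 11 were measured, had 0 members past the test over all genes or over the list alone. Their changes ran from -0.27 for Nfkb2 to 0.31 for Nfkbiz, with Rela at -0.18, Bcl3 at -0.19, Rel at -0.10, Nfkbia at -0.08, Nfkbib at 0.03, Ikbkg at 0.06, Relb at 0.07, Nfkbie at 0.12 and Ikbkb at 0.16. A dimmer probe of Ikbkb differed by -0.11. The list as a whole had a median of 0.03 with a mean of -0.01 (camera adjusted p = 0.909). Among 24 NF-kB target genes, 0 passed over all genes and 1 over the list alone, the matrix protease Mmp9 at -1.51. The chemokine Cxcl10 differed by -0.47, the adhesion molecule Vcam1 by -0.40 and the cytokine Il1b by 0.23, and the list median was 0.06 (camera adjusted p = 0.656). Cxcl10 and Il1b lay below the median of all probes, 5.80, in every array. In the list 14 members had a higher mean and 10 a lower one. The largest higher differences, named after their values were seen, were those of Ptgs2 (1.41) and Lcn2 (1.05). In obstructed replicates 1 and 2 Ptgs2 lay at -0.67 and 3.49, and Lcn2 at -0.04 and 2.14.

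Genes of smooth muscle contraction were lower in obstructed bladders as a list. Skeletal muscle genes, described with the cell types, were lower too, in 13 of 13 means with a median of -0.20. Of 22 contractile genes measured, 18 had a lower mean after obstruction. The 4 with a higher mean, named after their values were seen, were Synpo2 (0.39), Des (0.14), Cald1 (0.08) and Tagln (0.07). In obstructed replicate 1 they lay at 0.97, 0.40, 0.24 and 0.49. In obstructed replicate 2 they lay below the sham mean, at -0.19, -0.11, -0.08 and -0.35. Over all genes 0 contractile genes passed, and 5 were lower when adjusted over the list alone. These were Csrp1, an actin-associated LIM protein (-1.17, SE 0.18), Casq2, a calcium-binding protein of the sarcoplasmic reticulum (-1.38, SE 0.32), Mylk, the kinase that activates smooth muscle myosin (-0.97, SE 0.26, at -0.57 and -1.38 in obstructed replicates 1 and 2), the transcription factor Srf (-0.80, SE 0.22), named after its values were seen, and Pcp4, a calmodulin-binding peptide (-0.61, SE 0.15). The contractile list had a median of -0.52 (camera adjusted p = 4.27e-06; adjusted p = 0.621 with an estimated correlation), and it was -0.37 in obstructed replicate 1, -0.83 in obstructed replicate 2 and -0.30 without sham replicate 2. Of 15 genes of contraction signalling and calcium handling, 14 had a lower mean, 0 passed over all genes and 4 were lower over the list alone. The calcium pump Atp2a2 differed by -1.09 (SE 0.19) and its regulator Pln by -1.22 (SE 0.17), the calcium release channel Ryr2 by -1.42 (SE 0.31) and the cyclic GMP phosphodiesterase Pde5a by -1.18 (SE 0.29), at -0.77 and -1.58 in obstructed replicates 1 and 2. The median of this list was -0.38 (camera adjusted p = 1.16e-05; adjusted p = 0.614 with an estimated correlation), at -0.33 in obstructed replicate 1 and -0.67 in obstructed replicate 2, the array with the higher accessory gland values.

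Among 20 ion channels and bladder receptors, 0 passed over all genes and 4 were lower over the list alone. The ATP receptor P2rx1 differed by -2.07 (SE 0.39), the endothelin receptor Ednrb by -1.76 (SE 0.40, at -1.17 and -2.35 in obstructed replicates 1 and 2), the cation channel Trpc4 by -1.45 (SE 0.18) and the neurokinin receptor Tacr2 by -1.42 (SE 0.22). In each of these the obstructed arrays lay below both sham arrays. Across the list the median was -0.11 (camera adjusted p = 0.214), and without obstructed replicate 1 the camera adjusted p was 0.00912.

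Genes of matrix and growth moved in both directions. Of 37 extracellular matrix genes, 1 rose over all genes, Ltbp2, and 5 were higher over the list alone. The others were elastin, Eln (1.98, SE 0.36), the collagen gene Col8a1 (1.35, SE 0.22) and the crosslinking enzymes Lox (0.92, SE 0.19) and Loxl2 (0.97, SE 0.22), of which Loxl2 was named after its values were seen. The median over the list was 0.03 and its mean 0.33 (camera adjusted p = 0.00694; adjusted p = 0.764 with an estimated correlation). The call was lost without obstructed replicate 1, with a camera adjusted p of 0.895, and without sham replicate 1, with 0.206, and the list median was 0.30 in obstructed replicate 1, -0.15 in obstructed replicate 2 and 0.12 without sham replicate 2. Of 26 hypertrophy and synthetic smooth muscle genes, 1 rose over all genes, Ankrd1, and over the list alone 4 were higher and 6 lower. The matricellular gene Ccn1 differed by 1.15 (SE 0.19), the binding protein Igfbp5 by -0.83 (SE 0.18) and skeletal actin, Acta1, by -1.30 (SE 0.28). Named after their values were seen, Ccn2 (1.32) and Bdnf (0.41) completed the genes that were higher over the list alone, and Igf2 (-1.15), Fhl2 (-1.08), Klf4 (-0.74) and Pdgfa (-0.74) those that were lower. Over all its members the list had a median of -0.05 and its mean 5.83e-04 (camera adjusted p = 0.909). Among 21 proteases and inhibitors of matrix turnover, 0 passed over all genes, while over the list alone the metalloprotease inhibitor Timp1 was higher (1.52, SE 0.24) and Mmp9 lower (-1.51, SE 0.22). Adamts1 and Adamts12 differed by -0.66 and -0.78. The median of this list was -0.06, its mean 0.05 and its camera direction higher (adjusted p = 0.656), so that the median and the test differed in sign. Without obstructed replicate 2 the camera adjusted p of this list was 0.0344.

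Stress genes were higher as lists. Of 18 genes of protein folding and secretory stress, 14 had a higher mean after obstruction and 0 passed over all genes or over the list alone. The disulfide isomerase P4hb differed by 0.79 (SE 0.18), the secreted factor Creld2 by 0.97 (SE 0.23), the translocon subunit Sec61b by 0.79, with a dimmer probe at 0.45, and Herpud1 by -0.63. The list median was 0.41 (camera adjusted p = 0.00138; adjusted p = 0.422 with an estimated correlation), at 0.21 in obstructed replicate 1 and 0.41 in obstructed replicate 2, where the accessory gland medians were 1.65 and 8.06. Sec61b lay at 0.46 and 1.11 in these arrays and Creld2 at 0.75 and 1.20. Of 22 heat shock and antioxidant genes, 0 passed over all genes and 2 were higher over the list alone, the metallothioneins Mt1 (0.91, SE 0.13) and Mt2 (1.20, SE 0.25). Gclc, an enzyme of glutathione synthesis, differed by 0.57 and the heat shock gene Hspa1a by -0.63. The median of this list was 0.16 (camera adjusted p = 0.0135; adjusted p = 0.422 with an estimated correlation), and the call was lost without obstructed replicate 1 (camera adjusted p = 0.210) and without sham replicate 1 (0.119). The list median was 0.30 in obstructed replicate 1 and 0.10 in obstructed replicate 2. Among 21 immediate early and AP-1 genes, 0 passed over all genes and 1 over the list alone, the transcription factor Maff (1.59, SE 0.23), with Egr2 at 0.46, Ier2 at 0.39 and Jun at -0.44. The list as a whole had a median of 0.01 (camera adjusted p = 0.341).

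Genes of mitochondrial metabolism were lower as lists. Of 37 oxidative phosphorylation genes, 33 had a lower mean after obstruction, while 0 passed over all genes or over the list alone. Subunits of the respiratory chain and ATP synthase differed by -0.84 (Ndufa5, SE 0.18), -0.47 (Atp5b, SE 0.12), -0.48 (Cox7c) and -0.53 (Cox6c), and the list median was -0.20 (camera adjusted p = 9.67e-05; adjusted p = 0.422 with an estimated correlation). Of 21 fatty acid oxidation genes, 18 had a lower mean, 0 passed over all genes and 1 was lower over the list alone, the fatty acid transporter Cd36 (-1.56, SE 0.29). The oxidation enzymes Hadh and Acadm differed by -0.73 and -0.61 and the carnitine transferase Cpt1b by -0.42, while dimmer probes of Hadh and Acadm, with means of 7.82 and 8.44, differed by -0.27 and -0.03. The median of this list was -0.16 (camera adjusted p = 0.00362; adjusted p = 0.422 with an estimated correlation). Markers of other tissues moved with both lists: adipocyte genes had a median of -1.03, with 13 of 14 lower and 11 lower over the list alone, Adipoq among them at -4.00, and skeletal muscle genes had a median of -0.20, with 13 of 13 lower. In obstructed replicates 1 and 2 the medians were -0.20 and -0.30 for oxidative phosphorylation, -0.19 and -0.23 for fatty acid oxidation, -1.08 and -1.04 for adipocytes and -0.22 and -0.38 for skeletal muscle. Without sham replicate 1 those of oxidative phosphorylation and fatty acid oxidation were -0.12 and -0.093, and without sham replicate 2 those of fatty acid oxidation and skeletal muscle were -0.28 and -0.37. In 22 glycolysis and hypoxia genes, 0 passed over all genes and 1 was lower over the list alone, the mitophagy gene Bnip3 (-0.79, SE 0.15). Pfkp and Egln3 differed by -1.07 and -0.39 and Hk2 by 0.65, and the list median was -0.13 (camera adjusted p = 0.312). In obstructed replicates 1 and 2 Pfkp lay at -0.48 and -1.67, Egln3 at -0.11 and -0.67 and Hk2 at 0.03 and 1.27.

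Cell division genes were lower as a list, with 28 of 34 having a lower mean and 0 past the test over all genes or over the list alone. Ccne1 differed by -0.51, Top2a by -0.56 (at -0.87 and -0.26 in obstructed replicates 1 and 2), Kif20a by -0.39 and Ccna2 by -0.37. Their list median was -0.18 (camera adjusted p = 0.00829; adjusted p = 0.463 with an estimated correlation), and without obstructed replicate 2 the call was lost (camera adjusted p = 0.0593), as it was without sham replicate 2 (0.0612). The list median was -0.11 in obstructed replicate 1 and -0.23 in obstructed replicate 2. Ribosomal protein genes, 35 of which were measured, had 0 past the test over all genes or over the list alone and a median of 0.03 (camera adjusted p = 0.630), with Rps19 at -0.45, Rps14 at -0.17, Rpl37 at 0.15 and Rpl15 at -0.14. Interferon response genes were lower as a list, with 19 of 22 having a lower mean and 0 past the test over all genes or over the list alone. The guanylate-binding proteins Gbp3 and Gbp2 differed by -1.50 (SE 0.31) and -1.42 (SE 0.38, at -0.88 and -1.95 in obstructed replicates 1 and 2). Ifit3 and Ifit2 differed by -0.61 and -0.50. Their list median was -0.25 (camera adjusted p = 0.00311; adjusted p = 0.621 with an estimated correlation), and the call was lost without sham replicate 2 (camera adjusted p = 0.178).

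Circadian clock genes differed between the groups in both directions. Of 16 measured, 1 fell over all genes, Dbp, and over the list alone 3 were higher and 7 lower. The period genes, which repress the clock's activators, differed by -1.37 (Per1, SE 0.17), -1.74 (Per2, SE 0.23) and -1.41 (Per3, SE 0.21). The 3 genes that were higher, named after their values were seen, were Arntl, the activator also called Bmal1 (1.44, SE 0.22), the repressor Nfil3 (1.35, SE 0.33) and the activator Npas2 (0.47, SE 0.16, at 0.65 and 0.29 in obstructed replicates 1 and 2). In obstructed replicates 1 and 2 Dbp lay at -2.13 and -2.36 from the sham mean, Per1 at -1.39 and -1.35, and Arntl at 1.62 and 1.26. Across the list the median was -0.38 (camera adjusted p = 0.00278; adjusted p = 0.422 with an estimated correlation), at -0.16 in obstructed replicate 1 and -0.59 in obstructed replicate 2.

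**Figure D2:**
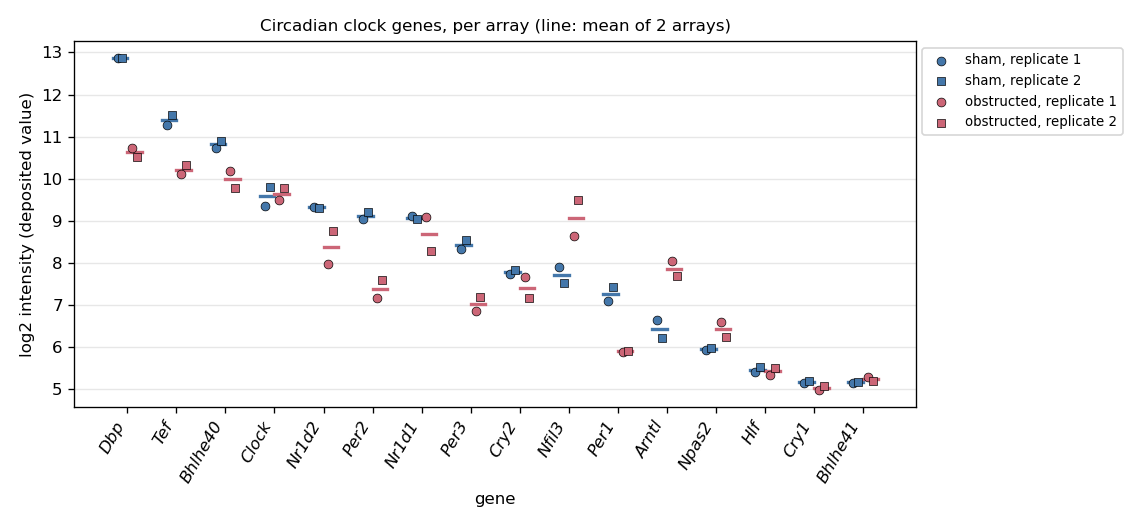
Deposited log2 intensity (vertical axis) of the circadian clock genes (horizontal axis) in each array, with sham in blue, obstructed in red, circles for replicate 1 and squares for replicate 2; lines are means of 2 arrays. Dbp and the 3 period genes lie lower in both obstructed arrays than in both sham arrays, and Arntl, Nfil3 and Npas2 lie higher.

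Markers of the other cell types that a bladder sample could hold were read from the same fit. Secretory genes of the male accessory glands, seminal vesicle and prostate, had the largest list median, 5.19, with all 16 measured members having a higher mean after obstruction. Over all genes 0 passed, and over the list alone 6 were higher, Defb50, Svs2, Msmb, Svs5, Svs4 and Spink1. Svs2, a seminal vesicle secretory protein, measured 5.39 and 5.21 in the sham arrays, 9.16 in obstructed replicate 1 and 14.95 in obstructed replicate 2. Msmb, a prostate secretory protein, measured 5.51 and 5.39 in sham and 8.71 and 14.12 after obstruction, and the defensin Defb50 measured 5.68 and 5.15 in sham and 9.30 and 12.93 after obstruction. Sbp, a prostate secretory gene, was high in 1 of the sham arrays too, at 11.91 in sham replicate 1 and 5.89 in sham replicate 2, against 12.99 and 15.32 after obstruction. Spink1, a protease inhibitor named after its values were seen, measured 11.93 and 6.86 in sham and 13.72 and 14.92 after obstruction. The list passed camera (adjusted p = 1.53e-11; adjusted p = 0.475 with an estimated correlation), with medians of 1.65 in obstructed replicate 1 and 8.06 in obstructed replicate 2.

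**Figure D3:**
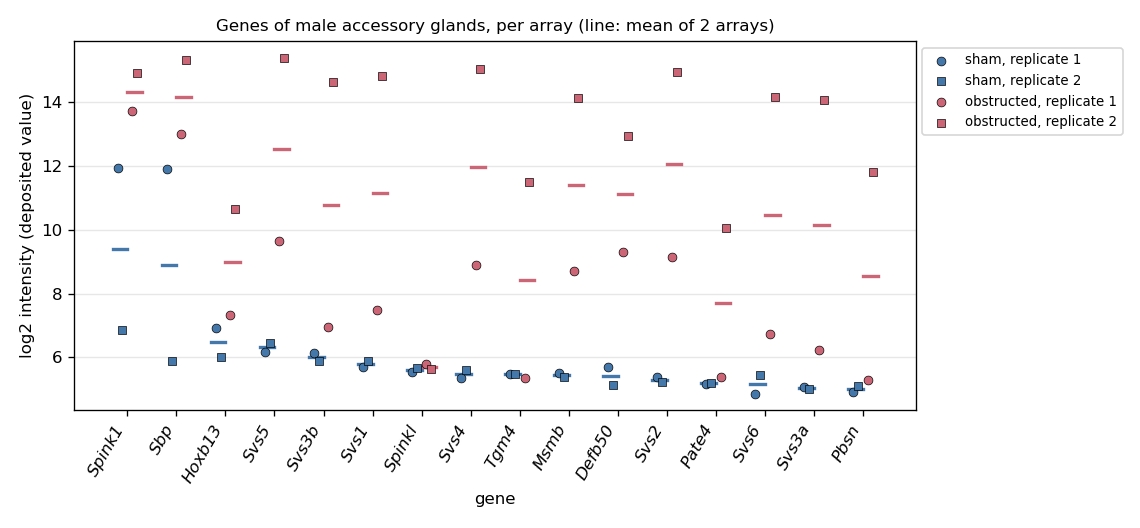
Deposited log2 intensity (vertical axis) of the genes of male accessory glands (horizontal axis) in each array, with sham in blue, obstructed in red, circles for replicate 1 and squares for replicate 2; lines are means of 2 arrays. Most genes lie highest in obstructed replicate 2, and Spink1 and Sbp are also high in sham replicate 1, at 11.93 and 11.91.

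Adipocyte genes were lower as a list in both obstructed arrays. Of 14 measured, 13 had a lower mean, 0 passed over all genes and 11 were lower over the list alone. Besides Adipoq (-4.00, SE 0.38) and Pck1 (-2.73, SE 0.36), the lipid droplet genes Cidec and Cidea differed by -2.09 and -1.12. The sham arrays themselves differed, sham replicates 1 and 2 being at 10.56 and 9.44 for Adipoq, 8.61 and 7.57 for Pck1 and 8.53 and 7.45 for Cidec. They were closer for Cidea, at 6.89 and 6.71. In each of these genes both obstructed arrays lay below both sham arrays. The median over the list was -1.03 (camera adjusted p = 2.55e-13; adjusted p = 0.422 with an estimated correlation), at -1.08 in obstructed replicate 1 and -1.04 in obstructed replicate 2. Skeletal muscle genes had a lower mean in 13 of 13 measured, with 1 that fell over all genes, Tcap, and 4 lower over the list alone, namely Tcap, Tnnt3 (-2.36, SE 0.28), Acta1 (-1.30, SE 0.28) and the creatine kinase Ckm (-1.43, SE 0.37, at -0.87 and -1.98 in obstructed replicates 1 and 2). Over all its members the list had a median of -0.20 (camera adjusted p = 9.67e-05; adjusted p = 0.422 with an estimated correlation), at -0.22 in obstructed replicate 1, -0.38 in obstructed replicate 2 and -0.37 without sham replicate 2.

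Urothelial genes, which mark the lining of the bladder, had 16 of 23 means higher after obstruction and 0 past the test over all genes or over the list alone. Krt14, a keratin of basal cells, differed by 1.31, at 0.42 in obstructed replicate 1 and 2.20 in obstructed replicate 2, the array with the higher accessory gland values, Krt8 by 0.46, Elf3 by 0.51 and Ly6d by 0.32, while a dimmer probe of Elf3 differed by -0.24. The list median was 0.13 (camera adjusted p = 0.0304; adjusted p = 0.712 with an estimated correlation). It was -0.01 in obstructed replicate 1, without a call (camera adjusted p = 0.980), and 0.32 in obstructed replicate 2, and the call was also lost without sham replicate 1 (0.0708) or sham replicate 2 (0.104, median 0.078). Genes of Schwann cells and nerves were lower in 13 of 14 means, with 0 past the test over all genes and 1 lower over the list alone, the myelin gene Mbp (-2.22, SE 0.46). Prph, Cnp and S100b differed by -0.86, -0.35 and -0.24, and the list median was -0.24 (camera adjusted p = 0.00530, and 0.422 with an estimated correlation). The call of the nerve list was lost without sham replicate 2, though its median there was -0.25. Mesothelial genes were lower in 6 of 6 means, with 0 past the test over all genes and Lrrn4 lower over the list alone (-1.59, SE 0.40, at -0.97 and -2.20 in obstructed replicates 1 and 2). Msln, Bnc1 and Upk3b differed by -0.81, -0.67 and -0.23, and the list median was -0.61 (camera adjusted p = 0.0135; adjusted p = 0.621 with an estimated correlation). Without obstructed replicate 2 that call was lost (camera adjusted p = 0.0833), as it was without sham replicate 1 (0.181), with list medians of -0.22 in obstructed replicate 1, -1.20 in obstructed replicate 2 and -0.34 without sham replicate 1. Red blood cell genes were lower in 5 of 5 means, with 0 past the test over all genes or over the list alone, and had a median of -0.75 (camera adjusted p = 0.0339; adjusted p = 0.712 with an estimated correlation). The globin genes Hba-a1, Hbb-bt and Hbb-b2 differed by -1.22, -0.98 and -0.75 and Slc4a1 by -0.37, and the list median was -0.04 in obstructed replicate 1 (camera adjusted p = 0.980) and -1.54 in obstructed replicate 2, the call being lost without sham replicate 1 too (0.181, median -0.49).

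The remaining cell type lists did not pass camera with all 4 arrays. Interstitial and pericyte genes had a median of 0.17 over 9 genes (adjusted p = 0.395), and 0.60 with a call on the higher side in obstructed replicate 1 alone (0.0125). Of these 0 passed over all genes, and Kit, the receptor of interstitial cells and mast cells, was lower over the list alone (-2.02, SE 0.21, limma adjusted p = 0.0776 over all genes), while Rgs5, Higd1b and Notch3 differed by 0.97, 0.58 and 0.32 and a dimmer probe of Rgs5 by 0.15. In the next 6 lists 0 members passed over all genes or over the list alone. Macrophage and monocyte genes had a median of 0.00 over 19 genes and a mean of -0.11 (camera adjusted p = 0.999), with Cd163 at -1.29, Mrc1 at -0.96, Cx3cr1 at 0.79 and Fcer1g at 0.15. Their median was 0.40 in obstructed replicate 1 and -0.58 in obstructed replicate 2, and each array alone against sham passed camera, in opposite directions (adjusted p = 6.21e-05 and 5.56e-05). Genes of T, B and NK cells had a median of 0.00, on the lower side by -0.002, and a camera direction on the higher side (15 genes, adjusted p = 0.959), with Klrd1 at -0.49, Nkg7 at -0.34, Cd4 at 0.13 and Gzmb at 0.11. Neutrophil genes had a median of 0.05 (10 genes, camera adjusted p = 0.461), with Il1r2 at 0.69, Camp at 0.21, Csf3r at 0.15 and Mpo at -0.31. Mast cell genes had a median of 0.49 (7 genes, camera adjusted p = 0.525), at 1.38 in obstructed replicate 1 and -0.14 in obstructed replicate 2. Tpsb2 differed by 0.75, at 1.60 and -0.10 in these arrays, Mcpt2 by 0.16, Ms4a2 by -0.18 and Hdc by -0.22. Mcpt2, Ms4a2 and Hdc lay below the median of all probes, 5.80, in every array. Without genes whose mean lay below it, the list medians in obstructed replicates 1 and 2 were 1.78 and -0.52. Endothelial genes had a median of -0.05 (17 genes, camera adjusted p = 0.610), and -0.28 with a call in obstructed replicate 2 alone (0.00737), with Tek at -0.71, Sox17 at -0.39, Kdr at -0.21 and Plvap at 0.36. Fibroblast genes had a median of -0.12 (10 genes, camera adjusted p = 0.681), and -0.40 with a call in obstructed replicate 2 alone (0.0157), with Lum at -0.78, Dpt at -0.75, Dcn at -0.29 and Pi16 at 0.48.

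In all, 17 of the 34 lists passed camera with its preset correlation, 12 lower and 5 higher. With the correlation estimated per list, 0 lists passed (smallest adjusted p = 0.422, with 2 lists at an unadjusted p below 0.05). By fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, 0 lists passed (smallest adjusted p = 0.249, with 6 lists at an unadjusted p below 0.05). By fry's mixed test, which takes changes in either direction, 9 lists passed. Of these, the oxidative phosphorylation, extracellular matrix, circadian clock and skeletal muscle lists had also passed camera. The ion channel, hypertrophy, protease, immediate early, and interstitial and pericyte lists had not. Of the 17 lists, 13 passed camera without obstructed replicate 2 and 15 without obstructed replicate 1.

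**Figure D4:**
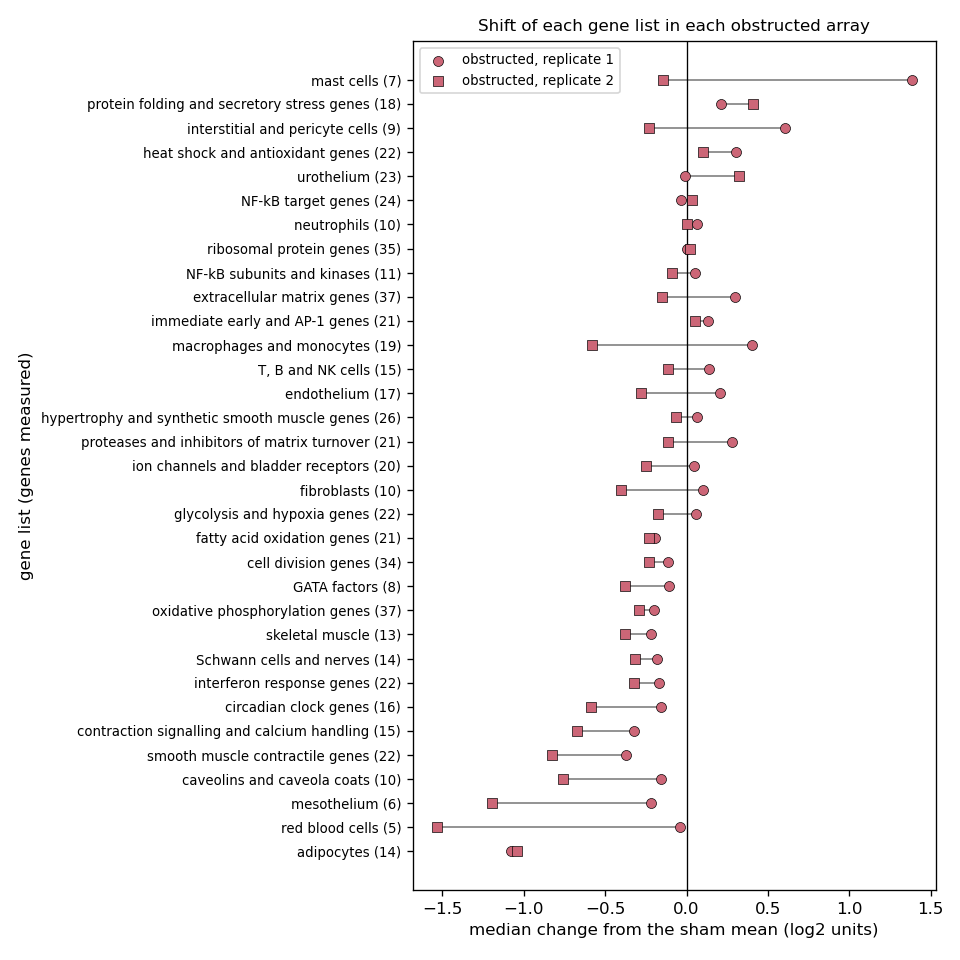
Median change from the sham mean (horizontal axis, log2 units) of each gene list (vertical axis, number of measured genes in brackets) in obstructed replicate 1 (circles) and obstructed replicate 2 (squares), with the accessory gland list, at 1.65 and 8.06, left out for scale. Adipocyte genes lie near -1.08 and -1.04, contractile and caveola genes lie lower in obstructed replicate 2, and macrophage genes lie on opposite sides of 0.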

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

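No test in this part was chosen after a result was seen: testing every probe on its own, named or not, was among the alternatives fixed before the data were examined. Probes with no gene name in the annotation used here take no part in the comparison of named genes, and 3 of them were higher after obstruction than in the sham arrays, which is why they are listed. With all 46657 probes tested by limma, 18 were called after Benjamini-Hochberg adjustment, and 7 of these were among the 24277 unnamed probes, 3 higher and 4 lower. Probe 101340121 had a mean log2 value of 5.89 in sham and 8.89 after obstruction, a change of 3.002 (SE 0.18, adjusted p = 0.00929). Probe 100780411 had means of 6.72 and 9.47, a change of 2.75 (SE 0.25, adjusted p = 0.0387). The third, a bright probe with means of 14.11 and 15.17, changed by 1.06 (SE 0.10, adjusted p = 0.0387). The largest change among the 4 lower ones was that of probe 2320736, at -5.83 (SE 0.30, adjusted p = 0.0089), from 12.18 to 6.35. Only group means were read for these 7 probes, without their values per array. The annotation used here does not pair these probes with genes, and no explanation was tested.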

How the results depend on the processing

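The weights per array were chosen after the data were seen; all other alternatives here were fixed before. The counts of 4 genes higher and 4 lower by limma changed to 0 and 0 with a floor of 50, 2 and 1 with the filter on dim probes, 7 and 11 with every probe tested, 2 and 4 without the trend, 6 and 11 with a robust trend, 0 and 0 without moderation, 7 and 16 at an adjusted p below 0.1, 4 and 8 with array weights, and 4 and 5 with the mean of all probes of a gene. The filter left 10579 genes and leaving out moderation leaves 2 residual degrees of freedom; in the other cases the cause was not tested. The weights were the same for both arrays of a group, 1.36 for sham and 0.733 for obstructed, and so could not tell arrays of 1 group apart. Of the 8 called genes, 6 remained called without the trend, 3 with the filter, and 8 with the mean of all probes, every probe, a robust trend and array weights. Quantile normalization, median centring and a minimum of 2-fold left the counts at 4 and 4; the first 2 moved almost nothing, since the columns already had the same distribution, and so say nothing about stability. With the replicate number as a block, 0 genes were higher and 1 lower, with 440 and 765 at an unadjusted p below 0.05. The labels give no reason to pair the numbers and deviations of same-numbered arrays correlated at -0.0165, so the numbers were not taken to pair the samples. With this block the caveola list, at a camera adjusted p of 0.0514 without it, had 0.0499.

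Leaving out 1 array at a time gave 0 to 519 genes higher and 0 to 780 lower. After moderation the fits had 13.8 degrees of freedom without obstructed replicate 1, 13.6 without obstructed replicate 2 and 4.52 without either sham array. By design the spread in each such fit comes only from the group that keeps 2 arrays. This is sham, correlated at 0.989, when an obstructed array is left out, and obstructed, correlated at 0.969, when a sham array is. The change of Cav1 ran from -0.86 to -0.26 and kept its sign in all 4 such fits; it passed the threshold in 1, without obstructed replicate 1. The count of lists past camera, 17 in the main setting, ran from 13 to 20 in these fits and from 14 to 18 with the floor, filter, probe mean, variance models and block, and fell to 0 with an estimated correlation and to 0 with fry.

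Some small changes turned direction, with causes that were not tested. With the filter on dim probes the median of NF-kB target genes was -0.030, of immediate early genes -0.073 and of macrophage genes -0.24, and with the mean of all probes the proteases and inhibitors of matrix turnover median log2 change was 7.6e-04. Among named genes, 21 changed sign when 1 array was left out, none of them past the threshold in the main setting. The ranges were -0.25 to 0.044 for Gata1, -0.077 to 0.53 for Gata2, -0.69 to 0.17 for Gata3, -0.55 to 0.31 for Gata5, -0.21 to 0.21 for Zfpm1, -0.93 to 0.14 for Zfpm2, -0.087 to 0.082 for Pacsin2, -0.67 to 0.12 for Nfkb2, -0.37 to 0.0093 for Rela, -0.27 to 0.42 for Relb, -0.23 to 0.026 for Rel, -0.25 to 0.31 for Nfkbib, -0.19 to 0.42 for Nfkbie and -0.0055 to 0.13 for Ikbkg. Among cell type markers they were -0.49 to 0.073 for Kdr, -0.065 to 0.36 for Csf3r, -0.10 to 1.60 for Tpsb2, -0.11 to 0.84 for Plvap, -0.78 to 0.0014 for Sox17, -0.68 to 0.11 for Dcn and -1.54 to 0.043 for Hbb-b2. List medians ranged from -0.58 to 0.40 for macrophages, -0.11 to 0.14 for T, B and NK cells, -0.088 to 0.054 for NF-kB subunits, -0.037 to 0.071 for NF-kB targets, -0.12 to 0.28 for proteases, -0.030 to 0.13 for immediate early genes, -0.28 to 0.21 for endothelium, -0.15 to 0.30 for extracellular matrix, -0.14 to 1.38 for mast cells, -0.23 to 0.60 for interstitial and pericyte cells, -0.25 to 0.044 for ion channels, -0.10 to 0.063 for hypertrophy genes, -0.18 to 0.056 for glycolysis, -0.011 to 0.32 for urothelium and -0.40 to 0.10 for fibroblasts. No detection call was used, so that changes of dim genes are limited by an unknown background.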

Other observations

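All tests that weigh an explanation in this part were chosen after the results were seen, as was the choice of genes in its opening paragraphs. Each obstructed array was also set alone against the 2 sham arrays in limma, with the lone array assumed to vary like the sham arrays. In both of these comparisons 64 genes were higher and 132 lower, with 13 called in opposite directions, where independent lists of these sizes would share 5.20 and 8.58. The sham arrays are shared, which may add to the excess. In 20 simulations with no effect every array was given the spread of the sham arrays. The obstructed arrays correlated less with each other (0.969, against 0.989 for sham). These simulations can therefore not say how many shared genes to expect with no effect. Across genes, which are not independent replicates, the changes correlated at 0.438 against 0.332 simulated with no effect from the sham spread. Their covariance was 0.0823 against 0.0179, with the same limit.

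Outside the fixed lists, and apart from genes already named, the genes whose smaller change in these comparisons was largest were, among the higher ones, the macrophage elastase Mmp12 (2.35 in obstructed replicate 1 and 1.69 in obstructed replicate 2), the copper transporter Atp7a (1.64 and 1.71), Sprr2f, a small proline-rich protein (1.67 and 1.58), Chrdl2, a secreted chordin-like protein (2.63 and 1.496), the serine protease Tmprss11g (1.43 and 3.03) and Ext1, an enzyme of heparan sulfate synthesis (1.86 and 1.41). Among the lower ones they were Hp, the haemoglobin-binding protein haptoglobin (-1.94 and -2.27), the secreted glycoprotein Stc1 (-1.70 and -2.005), the oestrogen sulfotransferase Sult1e1 (-2.08 and -1.68), Vat1l (-1.81 and -1.66), the neuropeptide Npy (-1.64 and -2.097) and Mamdc2 (-1.63 and -2.30). In the same arrays the list medians were -1.08 and -1.04 for adipocyte genes and 1.65 and 8.06 for accessory gland genes.

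Genes of male accessory glands had far higher values in the obstructed arrays. In obstructed replicate 2, 15 of the 16 measured genes, all but Spinkl, lay at least 2 log2 units above the higher sham array, against 5 in obstructed replicate 1. Obstruction as the sole cause is argued against for Spink1 and Sbp, whose sham arrays differed from each other by at least 5.07 log2 units, more than the smaller change between the groups, 4.93. Tissue or RNA of these glands in the samples is a candidate explanation that the count of 15 restates and does not test, so that for the other genes it cannot be told apart from an effect of obstruction. Whether both arrays held the same mixture of glands stays open too. Each ratio of the excess over sham rests on 1 array a side, and no spread of these genes was measured. Over the 5 genes well above sham in obstructed replicate 1 the ratios ran from 13.2 for Defb50 to 78.2 for Svs4. This 5.91-fold range fell to 1.65-fold without Defb50, while Svs1 and Svs6, dimmer there, had ratios of 231 and 256. In obstructed replicate 2, 3 of the 5 genes lay within 1 log2 unit of the highest value, where a ceiling could lower their ratios.

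Contractile genes were lower as a list, with medians of -0.37 and -0.83 in obstructed replicates 1 and 2 (camera adjusted p = 4.27e-06; adjusted p = 0.621 with an estimated correlation), and caveola genes, which did not pass (camera adjusted p = 0.0514), had medians of -0.16 and -0.76, gland genes being highest in replicate 2. Even dilution of all bladder RNA as the sole cause in replicate 2 would lower all bladder genes alike. It is argued against by Upk2, Upk3a and Upk3b, urothelial plaque genes of which the last is also a mesothelial marker. They lay 0.79 log2 units above contractile genes in median change (exact permutation p = 0.00957 over genes of 1 array), and 0.26 above in replicate 1. The urothelial list, some of whose genes gland epithelium shares, lay 1.19 above in replicate 2. A fall of contractile genes apart from dilution would leave such a gap too, so dilution in part stays open. A smaller share of smooth muscle as the only change in the samples would move the other cell types alike. The medians of 10 cell type lists were compared, without urothelium, glands, fat and skeletal muscle. They spread over 2.04 log2 units in replicate 1 and 1.61 in replicate 2 (permutation p = 4e-05 and 0.0102), against 0.72 between the sham arrays (p = 0.0696). A smaller muscle share as the only change was already argued against by lists left out here. Adipocyte genes had medians of -1.08 and -1.04 and gland genes of 1.65 and 8.06. The spread of the 10 lists therefore adds little, and its permutation takes markers of 1 cell type in 1 array as independent. Whether a smaller muscle share lowered the contractile genes was not tested by these lists, none of which is of smooth muscle. In replicate 1 mast cell genes lay highest and mesothelial genes lowest, in replicate 2 neutrophil genes highest and red blood cell genes lowest, while the 3 plaque genes alone differed from macrophage genes by -0.60 and 0.71 without passing (exact permutation p = 0.157 and 0.0539). Caveola genes lowered on their own account and with the contractile genes cannot be told apart, with a difference of -0.049 over both arrays (permutation p = 0.887, bootstrap interval -0.37 to 0.77), and lower transcription, changed cell shares and gland RNA acting together all stay open. Unlike the tests of cell type markers, this comparison kept caveola genes below the median of all probes.

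Clock genes had shifted values in both obstructed arrays. Gland RNA in obstructed replicate 2 is argued against as the cause, since the median absolute change in obstructed replicate 1 was 0.853 times that in obstructed replicate 2 (0.785 and 0.921) and the list passed camera in replicate 1 alone (adjusted p = 8.82e-04), while the signed medians, -0.16 and -0.59 over members that go both ways, were not used to decide. Arntl, Npas2, Clock, Nfil3 and Cry1, 5 genes taken as opposite in phase to the others, had a mean change 1.59 above that of the other 11 (0.64 and -0.95), but this grouping was made after the values were seen and so tests nothing. Collection at another time of day and a clock altered by obstruction may each give such a shift. The labels give no time of collection, so these cannot be told apart.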
